A study of Gallus gallus with 8 samples.

How the data were processed

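The series holds CUT&Tag libraries from chicken (Gallus gallus) liver. CUT&Tag tethers the transposase Tn5, fused to protein A, to an antibody on chromatin in permeabilised cells, so that adapters are inserted near the bound protein and the tagged fragments can be sequenced. The series title gives the study's subject as Nrf2-regulated genes, and the primary antibody is not named in the sources used here. Nrf2 is the transcription factor that activates antioxidant and detoxification genes through antioxidant response elements. Per the labels, 4 libraries came from birds kept at normal temperature and 4 from birds kept at high temperature. The labels number the samples 1 to 4 in each group without saying that each is a separate bird, so the p-values measure the spread between these samples.

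Reads were trimmed with cutadapt 1.9.2 and aligned with Bowtie2 2.2.4, and galGal6 is the genome build named, per the submitters' processing notes. The authors deposited 1 peak list per library, with 5 fields per line and no header. Each line gives a chromosome, a start, an end, a peak name of the form that MACS writes, and a score. The score is the value the authors' peak caller gave each peak, and its scale is not given in the sources used here. The version of the peak caller, its thresholds, the handling of duplicate reads and any control library are also not given in the sources used here. Since each library has its own list, with its own intervals, peaks were taken as called separately in each library. Starts were read as counted from 0 and are printed counted from 1. The lists hold no read counts, so the sequencing depth behind a peak is unknown, and intervals on shares of peaks cover counting error only.

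The 8 libraries were grouped by the treatment in the labels. Peaks of all libraries that overlapped by at least 1 bp were merged into union regions, and a library held a region if at least 1 of its peaks lay in it. The merge gave the same number of regions as bedtools 2.31.1. Numbers of peaks, covered length and median peak width per library were compared between groups by a two-sided exact permutation test over 70 assignments of the labels, which cannot give a p-value below 0.0286. These p-values were adjusted by the Benjamini-Hochberg method over the 3 measures. Overlap of covered sequence was measured as the Jaccard index, the percentage of the bases covered by either library that both covered. Its mean within groups minus its mean between groups was tested one-sided over the 35 splits of the libraries into 4 and 4. Group-specific regions were defined as those held by at least 3 of 4 libraries of one group and 0 of 4 of the other. Each union region was also tested by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. These tests and definitions were fixed before the data were examined, except for the number of measures adjusted over. The plan set the adjustment over all library-level measures, with median width given beside covered length. It covers 3 because the planned measures that need an annotation or a sequence were not made.

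The overlap that chance gives was estimated from 200 sets in which the peaks of each library were shifted around each chromosome by a random distance, up to the highest peak end seen on it. The region code was tested on simulated data for the normal against high temperature comparison. It recovered 200 of 200 planted high temperature regions and 100 of 100 planted normal temperature regions. It also called 3 regions that were not planted, among 68579 in the simulation. The planted peaks overlapped by design on a simulated chromosome of their own, and the other peaks were shifted ones. These counts therefore check the code, and not its sensitivity or its rate of false calls in the real lists. Of 200 planted regions held by 4 of 4 against 0 of 4 libraries, 0 passed the adjusted Fisher threshold, since the smallest p-value of 0.0286 cannot survive adjustment over so many regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

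The regions named in the text were chosen by a fixed rule. It took up to 10 group-specific regions per direction and 10 regions held by all 8 libraries, each ranked by the mean of the authors' score over the libraries holding it. The rule also asked for named genes near peaks. A gene annotation and a sequence of galGal6 were not used here, and the gene table at hand describes another assembly, whose coordinates cannot be mixed with those of the peaks. The planned comparisons of promoter peaks, of gene lists, of sequence motifs, and of GC and repeat content were therefore not made, and regions are given by position.

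The alternatives tried were the upper 50% of peaks by score, equal numbers of peaks, assembled autosomes only, a minimum cover of 50% of a region, merging within 500 bp, a Jaccard index over union regions, 4 of 4 against 0 of 4 libraries, the replicate number as a block and the omission of each library. Alternatives with 1 common score minimum, without peaks of identical coordinates, with peaks wider than 250 bp, and without high temperature 1 and 3 together were added after the data had been examined. Where peaks of different libraries had identical coordinates, every copy was removed from every library.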

Results

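CUT&Tag peaks were listed for 4 chicken liver libraries at normal temperature and 4 at high temperature. The 8 lists held 69159 peaks in total, and the read depth behind them is unknown. Normal temperature 1, 2, 3 and 4 held 8262, 8968, 10090 and 10599 peaks. High temperature 1, 2, 3 and 4 held 7550, 7647, 8253 and 7790 peaks. Most peaks were very narrow, with a width of exactly 200 or 250 bp in 88.9% to 98.0% of peaks in 7 of the libraries and in 31.5% in high temperature 1. The lowest score in a list lay just above a multiple of 10 in every library, by at most 0.54, and the multiple was not the same in all of them. It was 80, 60, 110 and 110 in normal temperature 1 to 4 and 30, 120, 80 and 100 in high temperature 1 to 4. The lists were thus bounded at different scores, and the number of peaks in a list is not on a common scale.

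**Figure D1:**
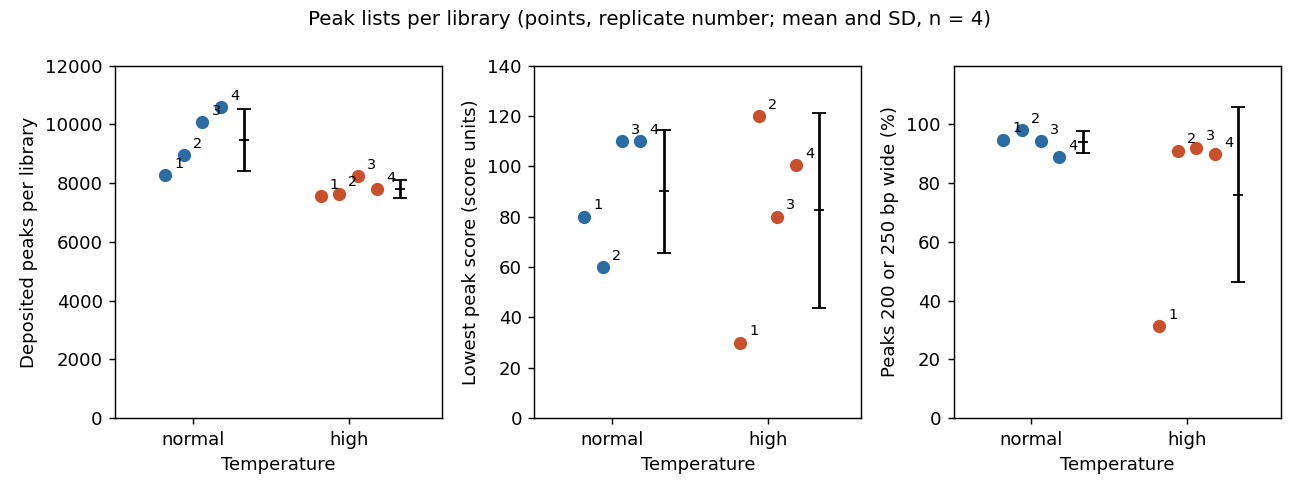
Number of deposited peaks (left), lowest peak score in the authors' score units (middle) and percentage of peaks 200 or 250 bp wide (right) in each library, by temperature group. Points are libraries with their replicate number, and bars are the mean and SD of 4 libraries. Peak numbers lie between 7550 and 10599 while the lowest scores run from 30.01 to 120.01, and high temperature 1 stands apart with 31.5% narrow peaks.

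The first comparison asked whether heat exposure changed the number and extent of CUT&Tag peaks in the liver. Normal temperature libraries held 9479.8 ± 1059.9 peaks (SD, n = 4) and high temperature libraries held 7810.0 ± 311 (SD, n = 4), a ratio of 0.824. Each of the 4 high temperature libraries held fewer peaks than each of the 4 normal ones. The two-sided exact permutation p was 0.0286, the smallest that this design allows. It was 0.0857 after adjustment over 3 measures, so the difference did not pass the threshold of 0.05. A single measure at the smallest p cannot pass this adjustment unless another measure reaches that p too. With 1 common score minimum of 120.01, on scores that are not known to share a scale, the libraries held 280 to 9370 peaks at normal temperature and 383 to 7647 at high temperature, and the exact permutation p was 0.629. Covered length was 2032 ± 259 kb at normal temperature and 2037 ± 583 kb at high temperature (SD, n = 4, exact permutation p = 0.971, adjusted p = 1.0). High temperature 1 alone covered 2909 kb, and without it the difference was -285 kb. Peaks wider than 250 bp covered 722 kb at high and 166 kb at normal temperature on average, a difference of 556 kb (two-sided exact permutation p = 0.286). The median peak width was 200 bp in 7 libraries and 343 bp in high temperature 1 (exact permutation p = 1.0). Among peaks wider than 250 bp the direction of the peak number was the opposite, with 333 ± 232 peaks at normal and 1473 ± 2172 at high temperature (SD, n = 4, exact permutation p = 0.343), of which high temperature 1 held 4730.

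A small set of regions carried peaks at both temperatures. The 69159 peaks merged into 66027 union regions, of which 14 were held by all 8 libraries, 10 by 7 libraries and 63 by at least 4. At most 6 regions were held by at least 4 libraries in any of the 200 sets of shifted peaks. Regions held by all 8 libraries numbered 0.94 on average and at most 1 in these sets. The 14 include a region on a scaffold, and scaffolds held up to 5 of the regions held by at least 4 libraries in a shifted set. The region on chromosome 9 from 5462139 to 5463515 (1377 bp) had the highest mean score and was among the 100 highest-scoring peaks in 7 of 8 libraries. Its neighbour from 5463524 to 5464219 (696 bp) was among the 100 highest-scoring peaks in 8 of 8. The region on chromosome 14 from 129956 to 131779 (1824 bp) held the highest-scoring peak of the list in 4 libraries. On the same chromosome, the region from 172566 to 173236 (671 bp) and the region from 409234 to 413259 (4026 bp) were among the 100 highest-scoring peaks in 6 libraries each. The region on chromosome 27 from 293553 to 297842 (4290 bp), the region on chromosome 1 from 88467815 to 88470195 (2381 bp) and the region on chromosome 3 from 2473981 to 2476488 (2508 bp) were so in 7 libraries each. The region on chromosome 15 from 269148 to 271542 (2395 bp) was so in 6 libraries, and the region on chromosome 22 from 112320 to 117999 (5680 bp) in 5. All coordinates are in galGal6, the build in the submitters' processing notes. The genes at these positions were not analysed here. With a common score minimum of 120.01, 4 of these 10 regions were still held by all 8 libraries, and 8 were so without identical-coordinate peaks. The other regions were then held by 6 or 7 libraries.

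**Figure D2:**
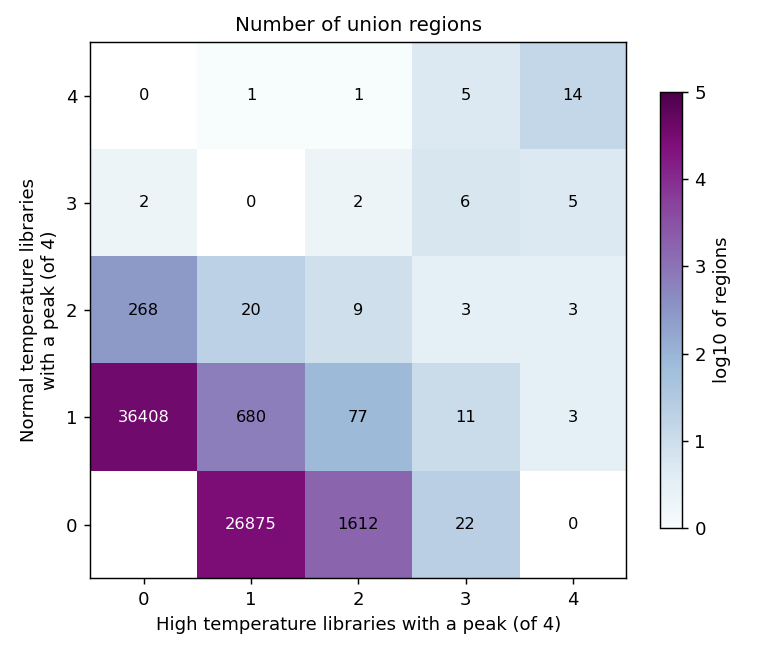
Number of union regions by how many of the 4 normal temperature libraries (vertical axis) and how many of the 4 high temperature libraries (horizontal axis) held a peak. Colour is the log10 of the number. Single-library regions make up 36408 and 26875 of the 66027 regions, 14 regions were held by all 8 libraries, and 0 regions were held by 4 of 4 libraries of one group and 0 of 4 of the other.

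Outside these regions, peaks rarely recurred from library to library. The counts and shares that follow include these regions unless stated. Of the 66027 regions, 63283 (95.8%) were held by 1 library only. Regions held by at least 2 libraries numbered 2744, or 4.16%, against a mean of 923 with shifted peaks. Of these, 1446 were held by high temperature 1 and 3 alone. Without regions of that pair alone, 1298 remained, against a mean of 888 and a maximum of 961 with shifted peaks, a ratio of 1.46. Leaving aside high temperature 1 with 3, a pair of libraries shared 54 to 140 regions, with a median of 81 over 27 pairs. That was 0.706% to 1.85% of the smaller list, and 1.85 to 3.08 times the mean of shifted peaks. With the 63 regions held by at least 4 libraries included, all 27 pairs shared more than the highest of the 200 shifted sets. Without these 63 regions, the median ratio to shifted peaks was 1.49 and the lowest 0.711. Pairs then lay on both sides of their highest shifted set. High temperature 2 and 3 shared 20 regions against 45, and normal temperature 2 and high temperature 1 shared 83 against 56. Peaks of exactly 200 or 250 bp overlapped a peak of another library in 3.03% to 3.86% of cases, and other widths in 7.81% to 25.0% of cases, leaving out the overlap between high temperature 1 and 3. Peaks wider than 500 bp did so in 47.1% to 72.7% of cases in 7 libraries and in 12.8% in high temperature 1.

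High temperature 1 and 3 shared far more than any other pair. They held 1563 regions in common, 20.7% of the smaller list and 38.9 times the mean of shifted peaks. In these, 937 peaks had the same start and the same end in both lists. In the other 27 pairs, at most 5 peaks had identical coordinates. These 937 peaks made up 12.4% of the peaks of high temperature 1 and 11.4% of those of high temperature 3.

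**Figure D3:**
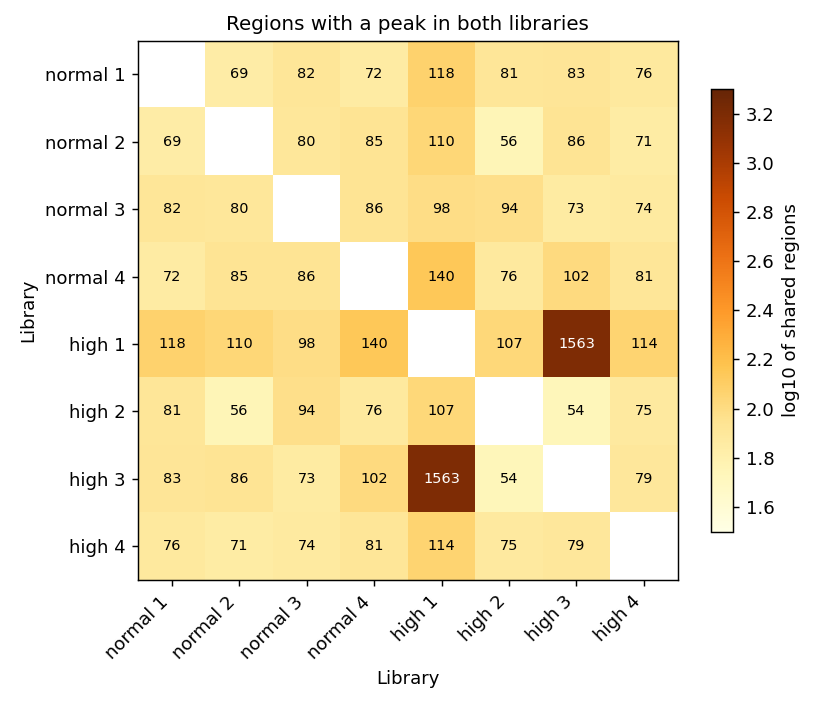
Number of union regions that held a peak in both libraries of a pair, for the 8 libraries in the same order on both axes, with the number in each cell and its log10 as colour. High temperature 1 and 3 shared 1563 regions, and every other pair shared between 54 and 140.

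The second comparison asked whether libraries of the same temperature were more alike than libraries of different temperatures. The Jaccard index averaged 1.99% within groups and 1.31% between groups, a difference of 0.678 percentage points. Of the 35 splits, 7 gave a difference as large (one-sided exact permutation p = 0.2), so the groups did not separate. The 6 normal temperature pairs averaged 1.02%, and the 5 high temperature pairs other than 1 with 3 averaged 1.62%. The difference was 0.283 without peaks of identical coordinates (one-sided exact permutation p = 0.114), -0.107 without high temperature 1 and -0.0865 without high temperature 3. It was 1.04 without normal temperature 1 and 1.04 without normal temperature 4, with one-sided exact permutation p of 0.0571 and 0.0286. Over the omission of each library this p, which is unadjusted, ran from 0.0286, the smallest that 35 splits allow, to 0.943.

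The third comparison asked which regions held peaks at one temperature only. There were 22 regions held by 3 of 4 high temperature libraries and 0 of 4 normal ones, and 2 regions held by 3 of 4 normal temperature libraries and 0 of 4 high ones. Shifted peaks gave a mean of 1.17 and a maximum of 5 for high temperature, and a mean of 0.95 and a maximum of 5 for normal temperature. All 22 high temperature regions held a peak of high temperature 1, and 17 held peaks of both high temperature 1 and 3, the pair with identical peaks. Without high temperature 1, 0 regions were held by the 3 other high temperature libraries and by 0 of 4 normal ones. The same count was 13, 5 and 4 without high temperature 2, 3 and 4. The normal temperature count was 0 without normal temperature 1, 2 or 4. No region was held by 4 of 4 libraries of one group and 0 of 4 of the other. Fisher's exact test over the 66027 regions called 0 regions at an adjusted p under 0.05 and 0 at an unadjusted p under 0.05, and its smallest p was 0.143.

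Of the 10 high temperature regions with the highest mean score, 3 were held by libraries 1, 2 and 3. They lay on chromosome 4 from 88902245 to 88902675 (431 bp), on chromosome 9 from 14945087 to 14945441 (355 bp) and on chromosome 2 from 102249286 to 102249629 (344 bp). Another 3 were held by libraries 1, 2 and 4. They lay on chromosome 1 from 154243913 to 154244792 (880 bp), on chromosome 33 from 6751115 to 6751414 (300 bp) and on chromosome 14 from 161876 to 165595 (3720 bp). The other 4 were held by libraries 1, 3 and 4. They lay on chromosome 2 from 87298367 to 87298655 (289 bp) and from 25202154 to 25202417 (264 bp), on chromosome 33 from 5867555 to 5867788 (234 bp) and on chromosome 3 from 37946572 to 37946963 (392 bp). With identical-coordinate peaks removed, 6 of these 10 regions were held by 1 library instead of 3, namely the 4 held by libraries 1, 3 and 4 and those on chromosomes 4 and 9. Since every copy is removed, a region whose peaks in libraries 1 and 3 coincide loses both of them in that setting. The rank also depends on which libraries hold a region, since median scores were 62.8, 152.6, 93.3 and 114.4 in high temperature 1 to 4, and 6 of the 9 regions with a peak of library 2 but 4 of the 13 without one ranked among the 10. None of these 10 regions was among the 100 highest-scoring peaks of any library. The region on chromosome 14 lies between the regions at 129956 and 172566 that all 8 libraries held. The 2 normal temperature regions lay on chromosome 1 from 72075262 to 72075684 (423 bp) and on chromosome 6 from 30739692 to 30739891 (200 bp). Both were held by normal temperature 1, 2 and 4. The one on chromosome 6 was held by 0 libraries with identical-coordinate peaks removed. That drop follows from the setting, since all its peaks had the same coordinates. For each of the 2 regions, presence in 3 libraries against 0 has a two-sided Fisher's exact p of 0.143.

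The share of peaks on each chromosome was compared between groups in 34 chromosomes, a comparison added after the data had been examined. Chromosome 3 held 11.1% ± 0.29 of peaks at normal and 10.2% ± 0.39 at high temperature. Chromosome 26 held 0.548% ± 0.011 and 0.668% ± 0.084, and chromosome 27 held 0.588% ± 0.064 and 0.793% ± 0.090 (SD, n = 4 each). Each of these 3 had a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and an adjusted p of 0.324. After adjustment 0 chromosomes passed the threshold. Over 34 chromosomes the smallest p passes only if many chromosomes reach it together, so this count is little evidence against a difference.

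Chromosomes Z and W are the sex chromosomes of birds, where males carry ZZ and females ZW. Peaks on Z made up 6.89% ± 1.57 at normal and 7.10% ± 1.01 at high temperature, and peaks on W 0.149% ± 0.190 and 0.0553% ± 0.0611 (SD, n = 4, exact permutation p = 0.771 and 0.457). Single libraries differed more than the groups. Normal temperature 4 held 46 peaks on W, or 0.434% of its list (95% exact Clopper-Pearson interval 0.318% to 0.578%), where the other 7 libraries held 1 to 11. It held 4.58% of its peaks on Z (interval 4.19% to 4.99%). High temperature 1 held 5.60% on Z (interval 5.09% to 6.15%) and 11 peaks on W, or 0.146% (interval 0.0728% to 0.261%). The other 6 libraries held 7.36% to 8.10% on Z.

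**Figure D4:**
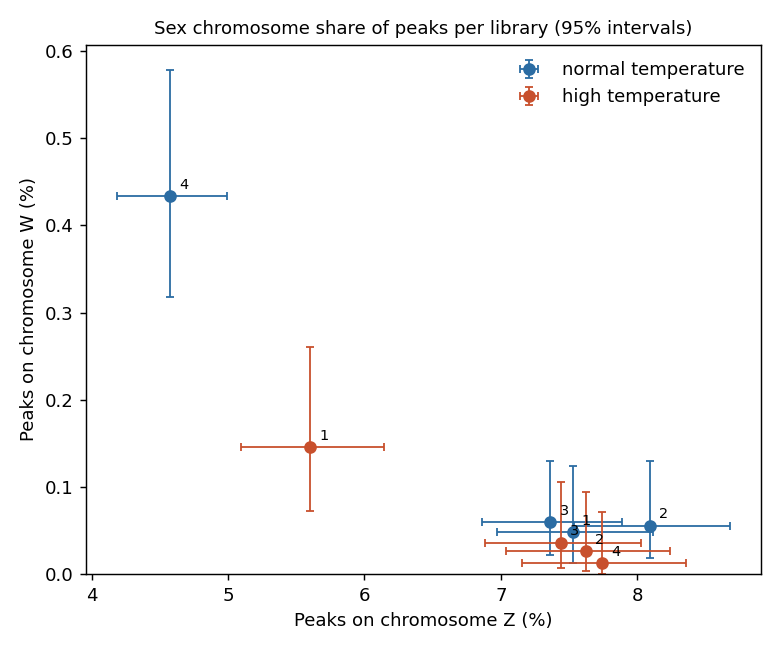
Percentage of peaks on chromosome W against percentage on chromosome Z in each library, coloured by temperature and labelled with the replicate number. Bars are 95% exact Clopper-Pearson intervals, which cover counting error only. Normal temperature 4 lies at 4.58% on Z and 0.434% on W, high temperature 1 at 5.60% and 0.146%, and the other 6 libraries lie between 7.36% and 8.10% on Z.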

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

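The tests in this part were chosen after the results were seen, except the count of splits, the sharing of the W regions and the comparison of Z shares within high temperature 1, which were set before their outcome was known. Single libraries were far from the other 3 of their group in 6 values, out of 16 groups of values examined, where chance sets apart about 1 in 20. High temperature 1 accounts for 5 of them. It covered 2909 kb against 1695 to 1798 kb. Its median width was 343 bp against 200 bp. It had 31.5% of peaks 200 or 250 bp wide against 89.8% to 92.1%. It held 5.60% of peaks on Z against 7.44% to 7.74%, and 2.93% on scaffolds against 0.603% to 0.850%. Normal temperature 4 held 0.434% of peaks on W against 0.0484% to 0.0595%. These values come from the same lists and are not independent.

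High temperature 1 and 3 shared 1563 regions. The overlaps argue against binding common to heat-stressed livers as the whole cause, since the other 5 high temperature pairs reached at most 3.08 times the shifted peaks against 38.9 times here. They argue against the wide peaks and low score minimum of high temperature 1 as well, since with the other 6 libraries it too reached at most 3.08 times. Molecules of one library read out in the other remain a candidate explanation, because 59.9% of the shared regions had identical starts and ends in both lists, against at most 5.88% in any other pair. Ranked by score in 4 equal parts, the peaks of high temperature 3 were identical in 29.5% of the highest part and in 4.60% to 5.72% of the others. In high temperature 1 the share was 29.3% in the highest part and 0.371% in the lowest. The identical peaks thus scored high in both lists, which does not tell the library they came from. The sequence reads, which could show whether the fragments are the same, were not used here.

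Normal temperature 4 and high temperature 1 differed from the rest on the sex chromosomes. High-signal sites on W listed in every library are argued against by the numbers, since each of the other 7 lists held 1 to 11 W peaks. The 46 W regions of normal temperature 4 could therefore not all be in another list, and the overlap count adds little. Of these 46 regions, 0 held a peak of another library above that library's own score minimum. A female bird among males is a candidate explanation for normal temperature 4, whose Z share was 0.597 times the mean of the other 3 normal libraries and whose intervals on Z and W lay outside those of the other 7. For high temperature 1, a female bird whose library also carries molecules of high temperature 3 is a hypothesis. Its peaks that overlap high temperature 3 held 6.83% on Z and 0 on W, and its other peaks 5.28% and 11. The two-sided Fisher's exact p was 0.0222 for Z over peaks, which are not replicates. High temperature 3 itself held 7.44% of its peaks on Z and 3 peaks on W. Peaks chosen for overlapping it are drawn towards those shares in any case, so this comparison cannot tell whether high temperature 1 is a female bird. The labels used here give no sex, and a mixed or mislabelled sample stays open.

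Each high temperature library held fewer peaks than each normal one. A score minimum set separately in each library cannot be told apart from a difference between the groups. At 1 common minimum the exact permutation p was 0.629, and high temperature 2 held 7647 peaks where normal temperature 2 held 280, yet the lowest scores of the groups overlapped, at 60.13 to 110.15 for normal and 30.01 to 120.01 for high temperature. A score may also depend on read depth, which is unknown here, and fewer bound sites under heat stays open and untested.

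For group-specific regions, 13 of the 35 splits of the libraries gave as many as the real 24, so chance is not excluded. The highest other split gave 43. In 15 splits high temperature 1 and 3 fall on the same side, and these include all 13, while splits that part them gave at most 15. This points to a structure of the samples, the peaks shared by high temperature 1 and 3, beside any difference between temperatures. For Fisher's exact test, the real count of regions at an unadjusted p under 0.05 was 0 and the highest other split gave 3. Any of the 35 splits is bound to give at least 0, so the splits decide nothing there.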

How the results depend on the processing

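The alternatives with a common score minimum, without identical-coordinate peaks, with peaks wider than 250 bp, and without high temperature 1 and 3 were chosen after seeing the data, and the others before. The difference in peaks per library (high minus normal) ran from -2076 to -1297 when each library was left out, where 3 against 4 libraries cannot give a p below 0.0571, and reversed to 1140.5 among peaks wider than 250 bp, a set held mostly by high temperature 1. With the replicate number as a replicate block the difference was -1669.8 (exact sign-flip p = 0.125, the smallest that 4 pairs allow), and the block changed no call. Whether the number pairs samples cannot be told. Peak shares per 1 Mb bin correlated weakly in all normal-high pairs, at -0.0402 to 0.0570 with the same number and -0.0821 to 0.0474 otherwise. The difference in covered length, 5.16 kb, reversed to -24.8 kb on assembled autosomes, -84.6 kb in the upper 50% of peaks by score, -103 kb without identical-coordinate peaks, -310.3 kb at the common minimum and -311 kb without high temperature 1 and 3, and ran from -285 to 119 kb with each library left out. It was 556 kb among wider peaks. The difference in median width was 0 bp without high temperature 1 and 3 and ran from 0 to 47.7 bp with each library left out. The Jaccard difference reversed to -0.217 percentage points without high temperature 1 and 3 and to -0.00672 among wider peaks, and ran from -0.107 (without high temperature 1) to 1.04 with each library left out. It was 0.283 without identical-coordinate peaks (one-sided exact permutation p = 0.114) and 1.03 in the upper 50% of peaks by score (p = 0.0857). It passed the threshold only without normal temperature 4, at 1.04 and a one-sided exact permutation p of 0.0286. This p is the smallest that 35 splits allow and is not adjusted for the number of alternatives. High temperature 1 and 3 were both kept in that run, so it does not show that the groups separate. Group-specific regions, 24 in all with 22 for high and 2 for normal temperature, were 54, 46 and 8 when peaks within 500 bp were merged. They were 15, 14 and 1 without identical-coordinate peaks, 9, 9 and 0 in the upper 50%, 8, 8 and 0 among wider peaks, 2, 2 and 0 at the common minimum, and 0, 0 and 0 for 4 of 4 against 0 of 4. Normal temperature regions numbered 1 with 50% cover and 1 with equal numbers of peaks. With each library left out, which asks for all 3 remaining libraries of that group, the totals ran from 3 to 27, the high temperature count from 0 (without high temperature 1) to 27, and the normal temperature count from 0 to 3. The adjusted Fisher count was 0 in every alternative run, with 0 to 13 regions at an unadjusted p under 0.05. The 12 group-specific regions named were followed only through alternatives that remove peaks or libraries, where a reversal is impossible, and not with 500 bp merging or 50% cover. Among peaks wider than 250 bp, 7 of the 10 named for high temperature and 2 of the 2 for normal temperature were held by 0 libraries. At the common minimum 2 of the 10 were still held by 3. The cause of these changes was not tested, except where a library or peak class was removed. The alternatives set for promoters, gene lists, motifs and GC content were not run, because no galGal6 annotation or sequence was used here. The unknown read depth limits every count of peaks.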

Other observations

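The tests and windows in this part were chosen after the results were seen. The regions that recurred across libraries were over-represented on scaffolds, on the small chromosomes and near chromosome starts. Of the 63 regions held by at least 4 libraries, 31 (49.2%) lay on chromosomes 11 to 33, where 19.0% of single-library regions lay (two-sided Fisher's exact p = 6.0e-08), and 0 lay on Z or W. Scaffolds held 14 (22.2%), against 0.809% of single-library regions (two-sided Fisher's exact p = 1.6e-16), and up to 5 in any of the 200 sets of shifted peaks. Of the 49 on assembled autosomes, 16 (32.7%) started within the first 500 kb of their chromosome, against 1.25% of 58221 single-library regions (two-sided Fisher's exact p = 9.6e-19). Chromosome 14 alone held 6 of the 16. Without chromosome 14 the shares were 23.3% and 1.24% (two-sided Fisher's exact p = 1.3e-10). Most of the 16 lay on chromosomes 11 to 33, where 500 kb is a larger part of a chromosome. The excess near starts and the excess on small chromosomes are thus not separate, and chromosome ends were not examined. Regions are not independent replicates.

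Several recurring regions lay close together. On chromosome 14, the regions at 129956, 172566, 348582, 357809 and 409234 were held by all 8 libraries, and the region from 363196 to 364072 by 4. On chromosome 9, the region from 5464691 to 5465145, held by 7 libraries, adjoins the 2 regions held by all 8. On chromosome 16, which carries the major histocompatibility complex and the ribosomal RNA genes of the chicken, the region from 521330 to 522094 was held by 7 libraries and the one from 520501 to 521132 by 4. Some recurring regions were uneven between temperatures. The region on chromosome 31 from 208823 to 210702 was held by 4 normal libraries and 1 high temperature library. The regions on chromosome 32 from 616569 to 618085 and on chromosome 18 from 11065468 to 11066567 were held by 1 normal and 4 high temperature libraries each. None of these 3 has a Fisher's exact p under 0.143. These regions were chosen after their values were seen.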
